A study of Rattus norvegicus with 6 samples.

How the data were processed

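Gene expression was measured on 6 single-colour NimbleGen oligonucleotide arrays, each hybridised with Cy3-labelled cDNA from 1 pool of rat tissue labelled as cerebellum. Each pool combined the tissue of 3 male Sprague-Dawley rats, per the labels. The alcohol group held 3 pools from rats given 40% alcohol by gavage at 15 ml/kg, and the control group held 3 pools from rats given the same volume of saline. The time between gavage and tissue collection was not given in the sources used here. The p-values measure the spread between pools, and how the rats of 1 pool varied cannot be seen in them.

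The authors deposited 1 file per array with a linear RMA intensity for each sequence ID; RMA is named in the submitters' processing notes without a version. RMA stands for robust multi-array average, which corrects background, equalises the arrays and summarises the probes of a sequence. Whether the 6 arrays were equalised together, the scanner software and the genome build were not given in the sources used here. The median intensity of an array lay between 213.2 and 232.8, and the intensity of the random-sequence control probes between 23.3 and 25.5. Each file held 26420 entries, of which 1 summarised 5651 random-sequence probes and was left out, so that 26419 features were tested. Of these, 26368 had 5 probes and 51 had fewer. The authors also deposited a value table of 18107 features, whose intensity values matched the per-array files within a relative difference of 9.1e-07. A test on the files showed that it holds exactly those features that reach an intensity of 50 on at least 3 of the 6 arrays, with 0 exceptions. An intensity of 50 therefore served as the floor under which a level is described as low and no fold is given.

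The intensities were put on the log2 scale without further normalization, because RMA as a method includes it. Names came from a table of rat RefSeq genes of the assembly GRCr8, matched through the gene identifier in the files for 20681 features. The files' own symbol was used for 2640 more and the description for 3098; 5430 features with a placeholder name stayed unnamed. No coordinates are given, because the sources used here name no build. Genes with near-identical copies, such as ribosomal protein-like loci, olfactory receptors, keratin-associated proteins and class I histocompatibility genes, may share signal on the same probes, and their identity is uncertain.

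Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the only term), with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. With 3 arrays against 3, an exact permutation test of 1 gene cannot go below p = 0.10, so single genes rest on the limma model. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9. Before the data were examined, 35 gene lists were fixed, covering stress and signalling responses, neurotransmission, metabolism, ribosomal and mitochondrial proteins, cell type markers, regional markers and olfactory receptors. Each list was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, using 1 feature for each of 24215 gene names, the one with the highest mean. The count of members past the threshold was also taken with adjustment over the list alone.

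The rule for named genes, also fixed before the data were examined, took features with 1 gene symbol, a mean above the median of all features and 3 alcohol values all above or all below the 3 control values. It named up to 12 genes past the threshold in each direction, or, where fewer than 5 passed, the 8 with the smallest p, which are then reported as not past the threshold. With the marker term, the condition on the 3 alcohol and 3 control values was replaced, after seeing the data, by separation within the 4 arrays and the same direction between the remaining 2. The rule also named up to 4 members of each list described and 20 genes chosen for the tissue and treatment, of which 1 is not reported here. Other genes are said to have been chosen after their values were seen.

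Some alternatives were fixed before the data were examined. For the values, these were the value table in place of the per-array files, centring of each array on its median, quantile normalization, leaving out each pool in turn, the replicate number as a block and a filter on dim features. For the tests, these were eBayes with trend and robust options, array weights, other thresholds (including treat against a fold of 1.2), the mean of all features of a gene, an inter-gene correlation estimated for each list, and the directional test fry. After the marker levels described in the results had been seen, a fit with a term for alcohol pool 2 and control pool 1, called the marker term, and a fit to the other 4 arrays were added. An inter-gene correlation estimated for each list was then also applied within these fits and within the other alternatives of the values or pools. The arrays themselves were compared before testing, and the number of identical log2 values between any pair was at most 6 of 26419.

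The procedure was tested on simulated data for 26419 features, with 50 changed features of each size. With group as the only term, 8% of features changed by 1 log2 unit passed the threshold, 54% of those changed by 2 and 86% of those changed by 4. With the marker term the shares were 40%, 88% and 98%. A list shifted by 0.25 was recovered in both designs and a list shifted by 0.1 in neither, and with no changed feature 0 passed. In the runs with changed features, 8 unchanged features passed with group as the only term and 6 with the marker term. Changed features came from above the median level, and 1 random list was shifted at each size. The noise was independent between features, so the runs do not cover lists whose members move together.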

Results

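Gene expression was profiled in rat tissue after acute alcohol intoxication. The series compared 3 pools of tissue labelled as cerebellum from rats given alcohol by gavage with 3 pools from rats given saline, and each pool combined 3 rats. Levels are log2 RMA intensities for 26419 features. Between 66.9% and 68.8% of features reached an intensity of 50 (5.64 on the log2 scale) on an array. The number of arrays limits the precision of every comparison.

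The arrays differed most in the markers of cerebellar neurons, and this difference did not follow treatment. Pcp2, a Purkinje cell protein, lay between 13.42 and 13.60 in alcohol pools 1 and 3 and control pools 2 and 3, but at 5.27 in alcohol pool 2 and 5.65 in control pool 1. Gabrd, a granule cell receptor gene, lay between 13.44 and 13.55 in the former 4 pools, at 7.94 in alcohol pool 2 and at 8.84 in control pool 1. Gabra6, the GABA-A receptor subunit typical of granule cells, lay between 13.97 and 14.18 in those 4 pools, at 7.49 in control pool 1 and under an intensity of 50 in alcohol pool 2. Neurod1, a granule neuron transcription factor, was at 5.41 and 6.79 in these pools against 14.21 to 14.39 elsewhere. Hoxa2, a hindbrain patterning gene, showed the opposite order, with 10.60 in alcohol pool 2 and 10.38 in control pool 1 against 4.16 to 4.56 in the other 4. Tph2, the serotonin-synthesising enzyme of neurons, was at 9.96 and 10.61 in these pools and under an intensity of 50 in the others. The serotonin transporter Slc6a4 was at 9.03 and 9.65, and likewise under 50 elsewhere. The median of the Purkinje cell list (15 genes) was 9.63 in alcohol pool 2 and 9.79 in control pool 1 against 13.32 to 13.44. That of the granule cell list (19 genes) was 9.32 and 9.69 against 13.09 to 13.32. The oligodendrocyte list (19 genes) had medians of 13.41 and 13.23 in these pools against 11.09 to 11.76. Snap25, a general synaptic protein, lay between 14.93 and 15.12 in all 6. The first principal component held 85.3% of the variance and set these 2 arrays apart, whereas the treatment group accounted for 5.31%. Neurod1, Hoxa2, Tph2, Slc6a4 and Snap25 were chosen after their values were seen.

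**Figure D1:**
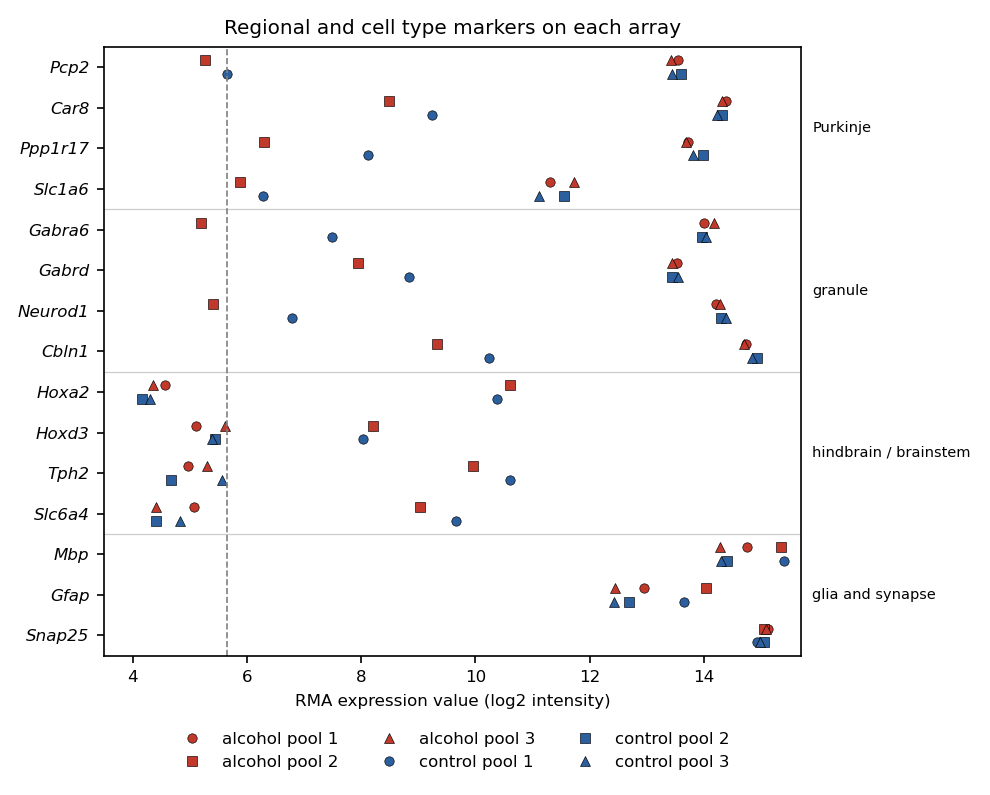
Log2 RMA intensity (horizontal axis) of single marker genes (rows) on each of the 6 arrays, with 1 point per pool, red for alcohol and blue for control, and the pool number given by the shape; the dashed line marks an intensity of 50. Alcohol pool 2 and control pool 1 lie apart from the other 4 pools for Purkinje, granule and hindbrain or brainstem genes, and Snap25 lies between 14.93 and 15.12 in all pools.

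The comparison of alcohol with saline asks which cerebellar genes respond to acute intoxication. Among the genes with the smallest p, Nfkbia, which encodes an inhibitor of NF-kappaB, had a level of 9.29 ± 0.26 (SD, n = 3) in alcohol pools and 8.46 ± 0.31 (SD, n = 3) in control pools, a difference of 0.83 (SE 0.24). The class I histocompatibility genes RT1-CE7 and RT1-N2 differed by 0.71 (SE 0.17) and 0.75 (SE 0.18). Hrh3, a presynaptic histamine receptor, was at 8.15 ± 0.07 (SD, n = 3) with alcohol and 8.80 ± 0.26 (SD, n = 3) in controls, a difference of -0.65 (SE 0.20). Zfhx2, a zinc finger homeobox gene, differed by -0.76 (SE 0.16) and the histone demethylase Kdm4a by -0.94 (SE 0.28). None of these genes passed the threshold: limma called 0 of 26419 features, with a smallest adjusted p of 1.00. In the simulated data, this fit called 8% of features changed by 1 log2 unit. The count of 0 therefore does not show that cerebellar genes did not respond.

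Without adjustment, 1030 features (3.90%) had a p under 0.05 in limma, 699 of them higher with alcohol and 331 lower, and 170 of these also differed by a fold of 2 or more, dim features included. Among features above the median level limma had 118 higher and 91 lower at an unadjusted p under 0.05 (1.58%), of which 26 differed by that fold. Chance gives a share of 0.05 on average, so that neither 3.90% nor 1.58% is an excess. The 3 alcohol values lay all above the control values for 1160 features and all below for 1153, together 8.76% of features against the 10% that chance gives. The counts were less even among features with a gene symbol and a mean above the median level, with 163 all above and 518 all below. Counted within the 2 kinds of pool instead, in a comparison chosen after seeing the data, the alcohol values lay above the control values both among the 4 pools with high cerebellar markers and between alcohol pool 2 and control pool 1 for 2856 features. They lay below in both for 3800, together 25.2% against the 16.7% that chance gives. Among features with a gene symbol above the median level, the counts were 811 above and 2205 below. Features are not independent, and these shares were not counted in other splits, so that neither share was tested against chance. The rest of the 8 genes with the smallest p and higher alcohol values under the naming rule were Rplp2l1 (1.09, SE 0.20), Rpl36l1 (0.66, SE 0.17), Krtap10-10l2 (0.95, SE 0.27) and the calcium channel Trpv6 (0.76, SE 0.23). The olfactory receptor Or2y13 was at 9.08 ± 0.14 with alcohol and 7.88 ± 0.38 in controls (SD, n = 3). The rest of the 8 with lower values were the molybdenum cofactor gene Mocs3 (-0.57, SE 0.16), the glycosyltransferase Galnt4 (-0.57, SE 0.18), Tmem179b (-0.74, SE 0.23), Kctd21 (-0.67, SE 0.22) and Zfp593 (-0.56, SE 0.19).

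**Figure D2:**
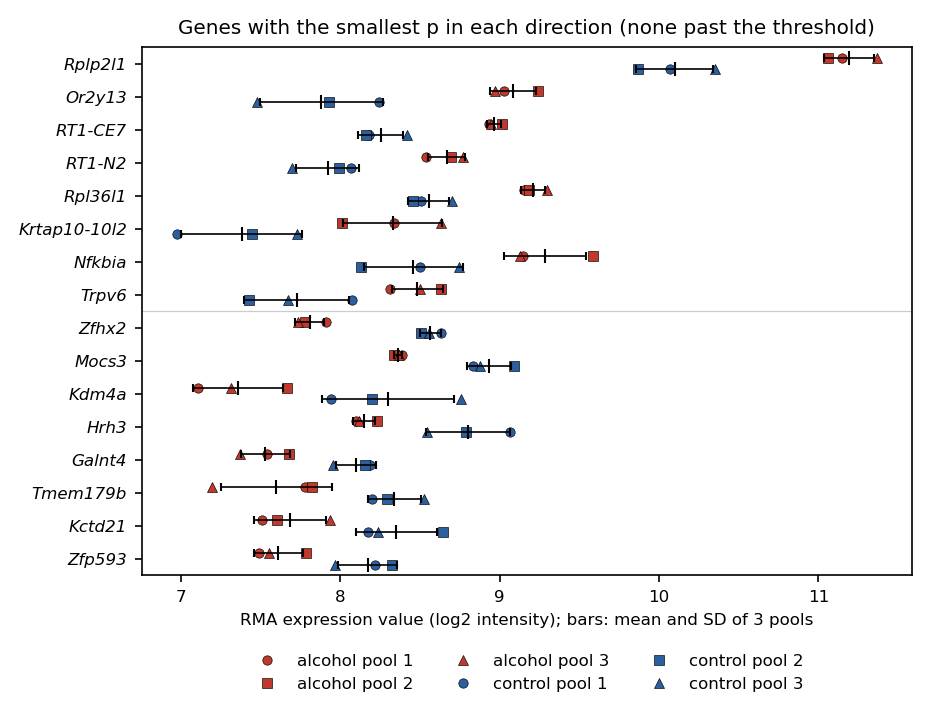
Log2 RMA intensity (horizontal axis) in each pool for the 8 genes with the smallest p in each direction under the naming rule; points are pools, and the vertical ticks with bars give the mean and SD of the 3 pools of a group. The alcohol and control points do not overlap for any gene, by construction of the rule, and none of these genes passed the adjusted threshold.

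Genes chosen in advance for their known place in the alcohol response or in the cerebellum did not pass the threshold either. Gabrb2 differed by 0.02 (SE 0.71), Gabrd by -0.31 (SE 1.93) and Gabra6 by -0.71 (SE 2.93), all subunits of the GABA-A receptor. Within the 4 pools with high cerebellar markers the difference was 0.09 for Gabra6 and -0.01 for Gabrd, and without 1 pool that of Gabrd ranged from -1.86 to 1.54. Gabra6 and the Purkinje gene Pcp2 lay under an intensity of 50 in alcohol pool 2, so that their group differences rest on a level that is only bounded there. The glutamate receptor subunit Grin1 differed by -0.10 (SE 0.40), the potassium channel Kcnma1 by 0.01 (SE 0.32), Pcp2 by -0.15 (SE 3.03) and the growth factor Bdnf by -0.36 (SE 0.23). Among activity and glucocorticoid genes, Fos differed by -0.49 (SE 0.98), Egr1 by 0.19 (SE 0.20), Fkbp5 by -0.05 (SE 0.23), Sgk1 by 0.12 (SE 0.57) and the clock gene Per1 by 0.11 (SE 0.26). Without 1 pool Fos ranged from -1.49 to 0.12 and Sgk1 from -0.36 to 0.60. Of the enzymes of alcohol and oxidant metabolism, catalase (Cat) differed by 0.23 (SE 0.47), Aldh2 by 0.00 (SE 0.36) and Hmox1 by -0.20 (SE 0.39). Cyp2e1 lay under an intensity of 50 on all 6 arrays. The glial genes Gfap, Mbp and Aif1 differed by 0.22 (SE 0.50), 0.09 (SE 0.40) and 0.15 (SE 0.61). Cat ranged from -0.07 to 0.70 without 1 pool, Gfap from -0.23 to 0.59 and Aif1 from -0.38 to 0.63. With the marker term, chosen after seeing the data, limma gave adjusted p values between 0.531 and 0.994 for the genes chosen in advance.

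Of the 35 gene lists, 2 fell with alcohol in limma's camera test. The cytosolic ribosomal protein list fell by a median of 0.12, with 69 of 78 members lower (adjusted p = 0.00110 in limma's camera). This call was lost with an estimated correlation (adjusted p = 0.996 with an estimated correlation). That setting called 0 lists in any of the 10 splits of the 6 arrays into 3 and 3. Such a loss, here and below, therefore does not decide whether a call holds. Rpl11 differed by -0.33 (SE 0.16) and Rps3 by -0.28 (SE 0.17), while Rps16, the 1 member with an unadjusted p under 0.05, went the other way, by 0.53 (SE 0.20). The mitochondrial respiratory chain list fell by a median of 0.10, with 55 of 69 members lower (adjusted p = 0.0481 in limma's camera). This call was lost as well (adjusted p = 0.996 with an estimated correlation). Its members include the complex I subunit genes Ndufb7 (-0.48, SE 0.18) and Ndufa6 (-0.23, SE 0.16). The ribosomal list deviated from its mean over all arrays by -0.05, -0.10 and -0.02 in alcohol pools 1, 2 and 3. In control pools 1, 2 and 3 the ribosomal list deviated by -0.04, 0.11 and 0.11. Control pool 1 thus lay below alcohol pool 3, and the groups overlapped. The respiratory chain list deviated by -0.08, 0.06 and -0.11 in alcohol pools 1, 2 and 3. It deviated by 0.13, 0.06 and -0.06 in control pools 1, 2 and 3, so that the groups overlapped. In both lists 0 members passed limma's threshold, over all features or adjusted over the list alone, and 1 member of each had an unadjusted p under 0.05. Leaving out control pool 3 gave an adjusted p of 0.0712 for the ribosomal list. Leaving out alcohol pool 1, alcohol pool 3, control pool 1 or control pool 2 gave 0.286, 0.329, 0.417 and 0.0825 for the respiratory chain, whose median without 1 pool ranged from -0.14 to -0.05, the latter without control pool 1. Over all alternatives limma's adjusted p ranged from 1.27e-06 to 1.00 for the ribosomal list and from 0.00146 to 1.00 for the respiratory chain. For each list, here and below, the upper end of such a range came from fry, which does not set a list against the other genes.

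**Figure D3:**
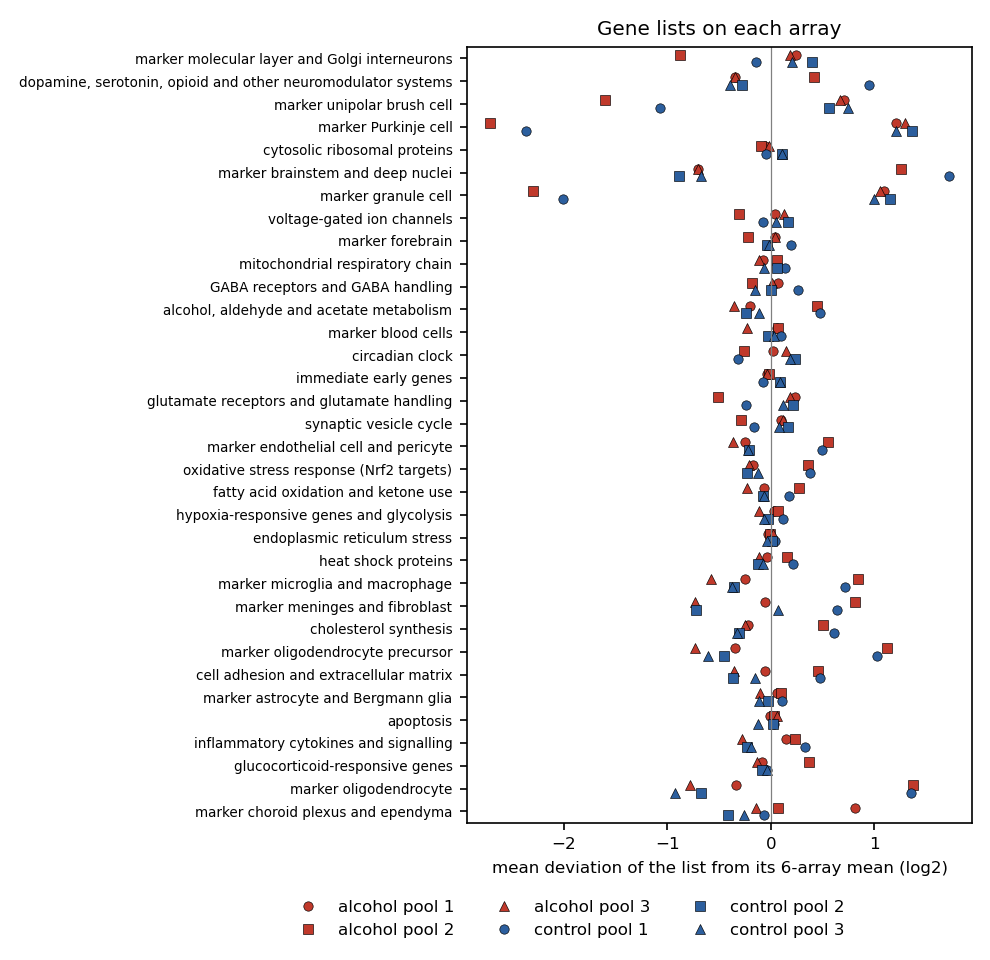
Mean deviation of each gene list from its 6-array mean in log2 units (horizontal axis), for 34 lists ordered by the difference between the group means; points are pools, red for alcohol and blue for control. The ribosomal list lies between -0.10 and 0.11 on all arrays, whereas the Purkinje, granule, oligodendrocyte and brainstem lists separate alcohol pool 2 and control pool 1 from the others.

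The other 33 lists did not pass, with adjusted p values from 0.0741 to 0.997 in limma's camera, and 0 members of any list passed limma's threshold over all features or adjusted over the list alone. Of the stress and signalling lists, the median difference was -0.06 for immediate early genes, 0.09 for glucocorticoid-responsive genes, -0.03 for the oxidative stress response, -0.01 for heat shock proteins, -0.02 for endoplasmic reticulum stress, 0.07 for inflammatory cytokines and signalling, 0.04 for apoptosis and 0.01 for hypoxia-responsive genes and glycolysis. The inflammatory list passed without alcohol pool 3 (0.14, adjusted p = 0.0330 in limma's camera) and without control pool 1 (0.15, adjusted p = 0.0245), and its median was -0.02 without control pool 3. The oxidative stress list passed without alcohol pool 2 (-0.23, adjusted p = 0.0302 in limma's camera). These calls were lost with an estimated correlation (adjusted p = 0.913, 0.818 and 0.820 with an estimated correlation). The oxidative stress list deviated from its 6-array mean by 0.36 in alcohol pool 2 and 0.38 in control pool 1, against -0.23 to -0.12 in the others. Leaving out either pool, here and below, therefore sets the difference in cerebellar markers against 1 group alone. Of the neuronal lists, the median difference was -0.00 for GABA receptors and GABA handling, -0.06 for glutamate receptors, -0.09 for voltage-gated ion channels, -0.03 for the synaptic vesicle cycle and -0.13 for dopamine, serotonin, opioid and other neuromodulator systems. Without 1 pool the median of the last list ranged from -0.42 to 0.17, and it passed without alcohol pool 2 (-0.42, adjusted p = 0.0169 in limma's camera) and without control pool 3 (-0.30, adjusted p = 0.00662), with a range of 0.00662 to 1.00 over all alternatives. Both calls were lost (adjusted p = 0.820 and 0.971 with an estimated correlation, against 0.996 for all 6 arrays). In the 4 pools with high cerebellar markers its median was 0.03 (adjusted p = 0.936 in limma's camera), and between alcohol pool 2 and control pool 1 it was -0.31. In this list the dopamine receptor Drd2 differed by -1.31 (SE 0.45), with 9.98 in control pool 1, 8.39 and 8.43 in the other control pools and 7.40 to 7.79 in the alcohol pools. Of the metabolic and structural lists, it was -0.02 for alcohol, aldehyde and acetate metabolism, 0.05 for cholesterol synthesis, -0.08 for fatty acid oxidation and ketone use, -0.05 for the circadian clock and 0.03 for cell adhesion and extracellular matrix. Without alcohol pool 2 the lists of alcohol metabolism (-0.18, adjusted p = 0.0218 in limma's camera), cholesterol synthesis (-0.27) and fatty acid oxidation (-0.16, adjusted p = 0.0458 for both) passed. Without control pool 1 those of cholesterol synthesis (0.37, adjusted p = 0.00735 in limma's camera) and cell adhesion (0.27, adjusted p = 0.0172) passed. These calls were lost as well (adjusted p = 0.820 without the former pool and 0.818 without the latter, with an estimated correlation). The olfactory receptors are a family not expected in this tissue and were listed for probes near background. They had a median of -0.01, and 87 of 1208 had an unadjusted p under 0.05 in limma, against 1030 of all 26419 features. The 59 receptors in the value table had a median of 0.32 and passed upward (adjusted p = 9.56e-13 in limma's camera), as did the 6 above the median level (0.50, adjusted p = 6.87e-06), and over all alternatives the adjusted p reached 1.00. These calls were lost as well (adjusted p = 0.981 and 0.391 with an estimated correlation). Of the 59, 3 reached an intensity of 50 on the alcohol arrays alone. Of the 24 that reached it on all 3 control arrays, counted after the values were seen, 23 were higher with alcohol (median 0.39). Whether this signal comes from receptor transcripts was not tested.

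Among cell type and regional markers, the choroid plexus and ependyma list had a median difference of 0.38 (adjusted p = 0.0741 in limma's camera), with 11 of 16 members higher with alcohol. The list deviated from its 6-array mean by 0.81 in alcohol pool 1, against 0.07 and -0.14 in alcohol pools 2 and 3. Without alcohol pool 1 its median was 0.26 (adjusted p = 0.286 in limma's camera; 0.00657 to 1.00 over all alternatives), without control pool 2 it was 0.23, without control pool 3 0.15 and without control pool 1 0.55. It passed in the value table (adjusted p = 0.0234 in limma's camera) and without alcohol pool 2, alcohol pool 3 or control pool 1 (adjusted p = 0.0305, 0.00657 and 0.0233). These calls were lost (adjusted p = 0.981, 0.820, 0.913 and 0.818 with an estimated correlation, against 0.996 for the per-array files of all 6 arrays). Its members Sostdc1 and Drc12 differed by 1.17 (SE 0.45) and 0.51 (SE 0.20). The median difference was -0.15 for Purkinje cells, -0.05 for granule cells, -0.32 for molecular layer and Golgi interneurons, -0.11 for unipolar brush cells, 0.05 for astrocytes and Bergmann glia, 0.16 for oligodendrocytes and 0.00 for their precursors. It was 0.05 for microglia and macrophages, -0.04 for endothelial cells and pericytes, 0.02 for meninges and fibroblasts, -0.11 for blood cells, -0.11 for brainstem and deep nuclei and -0.08 for forebrain. Without alcohol pool 2 the lists of Purkinje cells (1.12), granule cells (0.93), oligodendrocytes (-0.52), their precursors (-0.60), microglia (-0.43), endothelial cells (-0.33), meninges (-0.35) and brainstem (-0.79) passed, with adjusted p values from 0.00330 to 0.0470 in limma's camera. Without control pool 1 those of Purkinje cells (-1.18), granule cells (-1.06), oligodendrocytes (0.90) and brainstem (0.46) passed (adjusted p from 0.000104 to 0.0297). The oligodendrocyte (0.63) and meninges (0.36) lists passed without alcohol pool 3 (adjusted p = 0.0167 and 0.0176 in limma's camera), and the brainstem list without control pool 2 (-0.43, adjusted p = 0.0479). With an estimated correlation 0 lists passed without any 1 pool (lowest adjusted p = 0.818 with an estimated correlation). The median and the direction of the test differed in sign for heat shock proteins, granule cells and olfactory receptors (median below 0, test upward) and for oligodendrocyte precursors, microglia and hypoxia-responsive genes (median above 0, test downward). The mean lay below 0 for heat shock proteins, granule cells and hypoxia-responsive genes and above 0 for the remaining lists of these.

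With the marker term, added after the marker levels had been seen, the median SD of a feature was 0.216 in place of 0.348. Genes with a small p then included Fdcsp (1.13, SE 0.16), Foxf2 (0.76, SE 0.14), the macrophage gene Adgre1 (0.79, SE 0.14) and Taar7h (0.73, SE 0.12). With lower alcohol values they included Arhgap26 (-0.72, SE 0.16) and Kalrn (-0.53, SE 0.12), Lrrcc1 (-0.62, SE 0.12) and Zfp839 (-0.54, SE 0.12). Or2y13, Rplp2l1, Krtap10-10l2, RT1-CE7, Zfhx2, Hrh3, Mocs3 and Galnt4 were named again. In this fit a gene needed to differ in the same direction among the 4 pools with high cerebellar markers, without overlap, and between alcohol pool 2 and control pool 1. Of the newly named genes, Taar7h alone did not overlap between the 3 alcohol and 3 control pools. None passed: limma called 0 features with the marker term (smallest adjusted p 0.195; 0.130 to 1.00 over all alternatives). At an unadjusted p under 0.05 limma then had 2502 features, 1351 higher and 1151 lower. In the 4 other arrays alone limma called 0 features as well, with 2121 at an unadjusted p under 0.05. With the marker term, 5 lists passed in limma's camera, and none did with an estimated correlation (adjusted p = 0.982 with an estimated correlation). The oligodendrocyte list rose by a median of 0.16 (adjusted p = 0.0427) and the choroid plexus list by 0.38 (adjusted p = 0.0438). The molecular layer and Golgi interneuron list (adjusted p = 0.0367), the ribosomal list (adjusted p = 0.00111) and the respiratory chain list (adjusted p = 0.0427) fell. These limma calls at the preset correlation were all lost with an estimated one. In the 4 arrays alone, the ribosomal list fell by a median of 0.15 (adjusted p = 0.000842 in limma's camera), the oligodendrocyte list rose by 0.21 and the choroid plexus list by 0.47 (adjusted p = 0.0175 for both). These calls too were lost (adjusted p = 0.970 with an estimated correlation). The interneuron list had a median of -0.08 (adjusted p = 0.883) and the respiratory chain -0.10 (adjusted p = 0.128). Between alcohol pool 2 and control pool 1 the interneuron list differed by -0.62, the oligodendrocyte list by 0.02 and the choroid plexus list by 0.12. The ribosomal and respiratory chain lists each differed by -0.07 between these 2 pools. The oligodendrocyte list deviated from its 6-array mean by -0.34 in alcohol pool 1 and -0.78 in alcohol pool 3, against -0.68 in control pool 2 and -0.93 in control pool 3.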

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

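The fits with the marker term and to 4 arrays, and the estimated correlation within another alternative, were chosen after seeing the data; all others were fixed before the data were examined. The count of features past limma's threshold was 0 in each alternative with an adjusted p, also with treat, while an unadjusted p under 0.05 with a fold of at least 2 gave 170. Features at an unadjusted p under 0.05 numbered 1030, against 209 among features above the median level, 503 in the value table, 2502 with the marker term, 2121 in the 4 arrays and 2893 with array weights. Of these, 699 were higher and 331 lower, against 118 and 91 among features above the median level, 376 and 127 in the value table and 749 and 243 after centring; with a fold of 2 or more the counts were 26 and 112 in the former 2 of these and 196 after centring. The count of gene lists past the threshold was 2. It was 4 in the value table, 1 with centred arrays, 1 with quantile normalization, 5 with the marker term, 0 with an estimated correlation (also with the marker term, in the 4 arrays, in the value table, with the replicate block and without any 1 pool) and 0 with fry. Without 1 pool it ranged from 1 to 16, the latter without alcohol pool 2, against 9 without control pool 1. The ribosomal list kept a median below 0 in all 19 alternatives and passed in 14. The respiratory chain list did so in 19 and passed in 7, with adjusted p values of 0.120 after centring and 0.0689 after quantile normalization. Several of the 19, among them the replicate block, the marker term, the estimated correlation and fry, leave the differences unchanged. Their medians were therefore the same by design, and the fit to the 4 arrays is counted with both correlations. Leaving out alcohol pool 2 or control pool 1 leaves the other, with its low cerebellar markers, in 1 group alone, and list medians then turned. Without 1 pool they ranged from -1.18 to 1.12 for Purkinje cells, -1.06 to 0.93 for granule cells, -0.52 to 0.90 for oligodendrocytes and -0.60 to 0.51 for their precursors. They ranged from -0.43 to 0.35 for microglia, -0.35 to 0.36 for meninges, -0.27 to 0.37 for cholesterol synthesis and -0.79 to 0.46 for brainstem. The ranges were -0.18 to 0.12 for alcohol metabolism, -0.23 to 0.12 for oxidative stress, -0.02 to 0.15 for inflammatory genes, -0.16 to 0.14 for fatty acid oxidation, -0.26 to 0.27 for cell adhesion, -0.26 to 0.14 for the circadian clock and -0.33 to 0.22 for endothelial cells. The olfactory receptor median turned to 0.32 in the value table and 0.50 among features above the median level, which keep 59 and 6 of the 1208 receptors, and the list passed there (adjusted p = 9.56e-13 and 6.87e-06; 0.981 and 0.391 with an estimated correlation). Of the named genes, 6 values moved by more than 1 SD, 4 of them in the 4 arrays and 2 with array weights. The SD was that of the group-only fit, which holds the difference between the 2 kinds of pool. Gabra6 ranged from -2.88 to 2.26 and Pcp2 from -2.78 to 2.58 without 1 pool, yet neither counted as moved there. The marker term and the replicate block leave each difference unchanged. The count therefore says little about how firm a value is. The replicate block gave 0 features and 2 lists, and the respiratory chain then had an adjusted p of 0.0715, whereas the choroid plexus list passed (adjusted p = 0.0298), a call lost with an estimated correlation (adjusted p = 0.983). The deviations of pools sharing a number correlated at -0.83, -0.86 and 0.79 across features. The sign of each value follows which pools had low cerebellar markers, so that the check does not show whether the numbers pair the pools. A slide block was not run, because the files give no slide. Signal near that of the random-sequence probes limits what can be said of dim features.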

Other observations

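The tests of the tissue in alcohol pool 2 and control pool 1, of the ribosomal list in other splits and in the 4 arrays, and of a shared direction, with the splits under the marker term, were chosen after the values had been seen, as were the genes of the next paragraph and the use of the estimated correlation to weigh an explanation.

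Ttr, the transthyretin gene made by choroid plexus, was at 13.67 in alcohol pool 1 and between 6.78 and 9.04 in the other 5 pools, and the choroid plexus folate receptor gene Folr1 was at 8.35 there and between 4.28 and 6.86 elsewhere. In alcohol pool 1, 10 of the 16 choroid plexus and ependyma genes had their highest level among the 4 arrays with high cerebellar markers, and 4 of the 16 among all 6 arrays. Th, the rate-limiting enzyme of catecholamine synthesis, was at 11.15 in control pool 1 and 8.18 in alcohol pool 2, and between 5.21 and 6.37 in the other 4. Among genes singled out because their values were higher in all 3 alcohol pools, Ddit4 differed by 0.61 (SE 0.19), the kinase gene Sik1 by 0.86 (SE 0.26) and the phosphatase gene Dusp1 by 0.73 (SE 0.35), none past limma's threshold. The fixed lists that hold them and Nfkbia did not pass in limma's camera, among them the immediate early genes, with 18 members higher and 19 lower (adjusted p = 0.936), and the glucocorticoid-responsive genes (adjusted p = 0.899). Within the 4 arrays with high cerebellar markers the difference was 0.70 for Nfkbia, 0.47 for Ddit4, 0.78 for Sik1 and 0.40 for Dusp1, and between alcohol pool 2 and control pool 1 it was 1.08, 0.91, 1.03 and 1.39; the choice of these genes fixed the sign of both values.

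Alcohol pool 2 and control pool 1 had low Purkinje and granule markers, and a candidate explanation is that these pools held tissue from another part of the brain, such as the brainstem. Of 24 brainstem and deep nuclei genes in a list fixed in advance, 15 lay under an intensity of 50 on all 4 other arrays, and 7 of these (46.7%; Hoxa2, Hoxb4, Hoxb5, Hoxc4, Hoxd3, Tph2 and Slc6a4) reached 50 on both arrays, against 270 of 6598 features (4.09%). A failed array is argued against by the synaptic vesicle list, whose median lay only 0.18 log2 units under the lowest other array (-0.18). Degraded RNA cannot be judged from this list, because RMA equalises the arrays and no measure of RNA integrity was used. Cerebellum making up 25% or more of the RNA is argued against by Pcp2, Gabra6 and Gabrd, which kept at most 4.13% of their level. Alcohol as the cause is argued against by control pool 1, whose Purkinje median differed from the lower of alcohol pools 1 and 3 by -3.58. Which tissue was taken, and whether a smaller share of cerebellum was present, stays open.

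Of the 10 splits of the 6 arrays into 3 and 3, all 10 gave 0 features past limma's threshold, and 7 gave at least the real count of 2 gene lists, with a highest count elsewhere of 20; the splits are too few for a share under 0.05. The 4 splits that put alcohol pool 2 and control pool 1 on the same side gave 16 to 20 lists and 2663 to 4822 features at an unadjusted p under 0.05, against 1030 for the real split, which points to a structure of the samples. The ribosomal list itself also passed in 3 other splits (adjusted p = 0.00666, 0.0146 and 0.0224 in limma's camera, against 0.00110), once with a median difference of 0.123 in size against 0.119 for the real split. For the fall of the ribosomal and respiratory chain lists, the lowest adjusted p of a called list was 0.996 with an estimated correlation, but that test called 0 lists in any of the 10 splits, so that whether members moving together account for the calls cannot be told apart from an effect of alcohol. Alcohol pool 2 and control pool 1 as the whole cause are argued against by the ribosomal median of -0.15 in the 4 other arrays.

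A response to alcohol that both kinds of pool share is a hypothesis that was tested by setting the alcohol difference within the 4 arrays against that between alcohol pool 2 and control pool 1, which have no array in common. Across 12273 genes, which are not independent replicates, the Pearson correlation was 0.360 and 61.7% of genes had the same sign. The other 2 ways of splitting the 4 arrays gave -0.181 and 0.252. Only the size of these 2 values can be set against 0.360, because the side that is subtracted sets their sign. With the marker term, the real split gave 2502 features at an unadjusted p under 0.05, and it was the 1 of 6 splits within the 2 kinds of pool to do so, with a highest count elsewhere of 1443. Both sets of splits are too few for a share under 0.05, and the gene list counts did not single out the real split, with 5 lists against 4 to 12. Whether the shared direction comes from alcohol or from another difference between the pools cannot be told apart here.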
